A study of Mus musculus with 8 samples.

How the data were processed

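RNA from 4 NS-DADm and 4 WT liver samples of male mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with Trizol and a column kit, made into sense-strand cDNA with a whole-transcript kit and labelled with biotin. The values used were a table as deposited by the authors, with 28270 probe sets and 8 arrays. Per the submitters' processing notes, RMA and Partek were the tools the authors used, while their order, versions and settings are not given in the sources used here. The deposited values were taken as log2 intensities, and this scale was read from the values themselves, which run from 3.43 to 14.37. A fold change printed here is 2 to the power of a log2 difference, so it holds only if that reading is right. RMA corrects background, normalizes between arrays and summarises the probes of a set, and it compresses small differences at low intensity. The deposited columns were not identical in distribution. Array medians ran from 7.39 to 7.50 and array SDs from 2.02 to 2.09. No value was missing, no columns were identical, and every column matched 1 sample. No batch, scan date or detection call was given in the sources used here, so signal over background could not be judged per gene.

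Groups and replicate numbers came from the sample titles and genotype labels. Probe sets were named from a platform annotation of the array, with symbols updated by Entrez Gene identifier through a table of mouse genes on the GRCm38.p6 assembly. Of the 28270 probe sets 21780 named 1 gene, 1617 named several and 4873 were unnamed. Probe sets that named several genes or none entered no gene result. Each gene was represented by the probe set with the highest mean over the 8 arrays among those naming that gene alone, which gave 19935 genes, of which 19852 matched the table by identifier and 995 had more than 1 probe set. No filter on low values and no pseudocount were applied. The transcripts of the mutated corepressor genes were not analysed here.

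The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without an intensity trend, as a two-sided moderated test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A change of at least 1.5-fold was counted separately. Errors beside group means are SDs over 4 arrays, and SEs and 95% confidence intervals of fold changes come from the fit. The median SE of a log2 fold change was 0.070. Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over lists, for the 36 of 38 lists with at least 5 measured members. The lists held 612 members, of which 550 were measured and 62 were not. Within each list members were also adjusted over the list alone. The lists, the groups, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. That rule took all members of the NCOR/SMRT-HDAC3 complex, the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, leaving out predicted and clone names, and of each list up to 4 changed members per direction or, where none changed, the 2 members with the largest absolute log2 fold change, given as values.

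The alternatives were all probe sets tested separately, the mean of the probe sets of a gene, filters on low values at the median and at the 25th percentile, quantile normalization, subtraction of array medians, trended and robust variances, array weights, the replicate number as a block, a gene-by-gene test without shared variances, camera with an estimated correlation or on ranks, other thresholds, and each array left out in turn. The SD of each array as a covariate was added after seeing the data. The steps were tested on simulated data made from the real means and spreads, with 200 of 19935 genes changed in each of 10 runs. The sinusoidal endothelial markers were also lowered in each run and counted as changed. More genes were thus changed than the 54 called in the real data, which loosens the adjusted threshold. The recovery rates may therefore be too high for the real arrays. Noise was drawn independently for each gene, without correlation between genes or array-wide effects, so the rates may not hold for the real arrays. For simulated NS-DADm against WT samples, 82.1% of genes changed by 0.5 on the log2 scale were recovered, 98.1% of those changed by 1 and 100% of those changed by 2, and 5.04% of calls were false. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.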

Results

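Transcript levels were measured in 8 liver samples from male C57Bl/6 mice on Affymetrix Mouse Gene 1.0 ST arrays, which read most exons of a gene with short oligonucleotide probes. In 4 NS-DADm samples the corepressors NCOR and SMRT carried mutations of the deacetylase-activating domain, the part of each protein that binds HDAC3 and switches on its histone deacetylase activity. The other 4 samples were wild type (WT). Livers came from mice aged 10 to 12 weeks, kept on normal chow under 12 h of light and 12 h of dark, and were taken at zeitgeber time 10, late in the light phase. Array medians lay between 7.39 and 7.50 on the log2 scale. Pairs of NS-DADm arrays correlated at r = 0.993 to 0.998 across probe sets, pairs of WT arrays at 0.993 to 0.997, and pairs of 1 array of each group at 0.993 to 0.997. The labels do not state that each array came from a separate animal, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

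The comparison asked which liver transcripts differed between WT mice and mice in which neither corepressor can activate HDAC3. Within the NCOR/SMRT-HDAC3 complex, Tbl1xr1 (Entrez Gene 81004), a WD-repeat subunit, rose from 9.86 ± 0.13 in WT to 10.47 ± 0.10 in NS-DADm livers (log2, SD, n = 4 each), a log2 fold change of 0.61 (SE 0.078, adjusted p = 0.0118). Hdac3 itself was at 10.68 ± 0.11 in WT and 10.76 ± 0.10 in NS-DADm livers, a difference of 0.09 that did not pass the test (adjusted p = 0.828) and was 0.04 without NS-DADm replicate 1, 0.05 without WT replicate 3 and 0.13 without WT replicate 4. Tbl1x, the X-linked relative of Tbl1xr1, was 0.20 higher (adjusted p = 0.234) and Gps2 was 0.04 lower, at a log2 fold change of -0.04 (adjusted p = 0.964), but above 0 without NS-DADm replicate 3 or WT replicate 2. Of the 4 measured members of the complex 1 was higher over all genes, and 2, Tbl1xr1 and Tbl1x, when adjusted over the list alone. The transcripts of the mutated corepressor genes were not analysed here, so the genotypes rest on the labels. Without WT replicate 2 or 3 the change of Tbl1xr1 had an adjusted p of 0.0703 or 0.0501.

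The largest rise was in Cyp2b9 (Entrez Gene 13094), a cytochrome P450 that mouse liver makes mainly in females. It went from 6.35 ± 0.40 in WT to 9.62 ± 1.01 in NS-DADm livers, 9.67-fold (log2 fold change 3.27, SE 0.41, 95% confidence interval 2.37 to 4.18, adjusted p = 0.0102). Acnat2 (Entrez Gene 209186), of a family of acyltransferases that conjugate fatty acids to amino acids, rose 4.21-fold (log2 2.07, SE 0.23, adjusted p = 0.00493). Serpina7 (Entrez Gene 331535), which encodes thyroxine-binding globulin, rose 3.54-fold, from 9.06 ± 0.48 to 10.89 ± 0.12 (adjusted p = 0.00364). The acute phase gene Saa2 rose by 1.63 on the log2 scale, the steroid-synthesis cytochrome P450 gene Cyp17a1 by 1.59. Atp6v0d2, a subunit of the vacuolar proton pump, rose 2.83-fold (SE 0.15 on the log2 scale, adjusted p = 0.00364). Cd36, which encodes a fatty acid translocase, rose from 8.93 ± 0.41 to 10.22 ± 0.15, 2.43-fold (adjusted p = 0.013). The others of the 12 largest rises were Lcn2 (log2 1.29), Cyp2c38 (1.28), the monocarboxylate transporter family gene Slc16a5 (1.25), the acyl-CoA synthetase gene Acss3 (1.04) and Orm2 (0.996). Probes for Cyp2b9, Cyp2c38, Saa2 and Orm2 are open to signal from close paralogs, so the share of each copy is uncertain.

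Acnat2, Serpina7, Cyp17a1, Atp6v0d2, Slc16a5 and Orm2 stayed past the threshold whichever of the 8 arrays was left out. Without WT replicate 2 the adjusted p was 0.0696 for Cyp2b9, 0.0867 for Saa2, 0.172 for Lcn2, 0.0539 for Cd36, 0.169 for Cyp2c38 and 0.0867 for Acss3. Cd36 and Acss3 also missed the threshold without WT replicate 3 (adjusted p = 0.0534 and 0.0574), and Saa2, Lcn2 and Cyp2c38 missed it without 4, 5 and 3 further arrays. Trended and robust variances gave an adjusted p of 0.0863 for Cyp2b9 and 0.0855 for Saa2. Lcn2 missed the threshold under 6 processing alternatives (adjusted p = 0.0505 to 0.125) and Cyp2c38 under 3 (0.0548 to 0.105), not counting the test without shared variances, which called no gene.

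**Figure D1:**
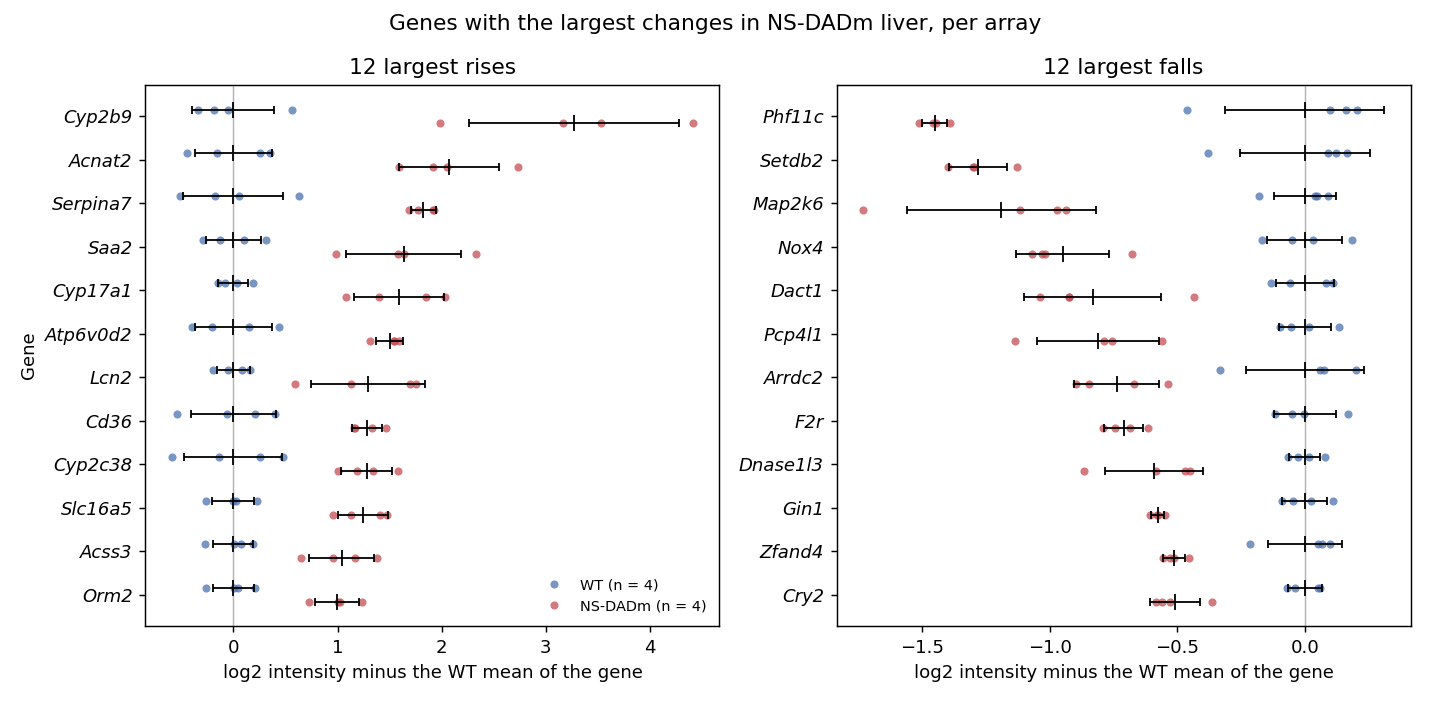
Log2 intensity minus each gene's WT mean (x axis) for the 12 genes with the largest rises and the 12 with the largest falls among the changed genes (y axis), with 1 point per array and black bars for the group mean ± SD (n = 4). For each gene the 4 NS-DADm arrays lie entirely above or entirely below the 4 WT arrays, as the rule that chose the genes required. The means are farthest apart for Cyp2b9, by 3.27.

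The largest falls were in the neighbouring genes Phf11c (Entrez Gene 628705) and Setdb2 (Entrez Gene 239122). Phf11c encodes a PHD finger protein and Setdb2 a SET-domain protein of the histone methyltransferase family. Phf11c fell from 10.12 ± 0.31 to 8.67 ± 0.05 (log2 fold change -1.45, SE 0.13, adjusted p = 0.00309) and Setdb2 from 10.14 ± 0.25 to 8.85 ± 0.11 (-1.28, SE 0.11, adjusted p = 0.00309). Map2k6, a kinase upstream of the p38 MAP kinases, fell by 1.19 on the log2 scale, and Nox4, an NADPH oxidase, fell by 0.95, from 10.12 ± 0.15 to 9.17 ± 0.18 (adjusted p = 0.00364). F2r, which encodes a thrombin receptor, had a log2 fold change of -0.71, the Wnt pathway regulator Dact1 one of -0.83 and Dnase1l3, a secreted nuclease, one of -0.59. Pcp4l1 (-0.81), Arrdc2 (-0.74), Gin1 (-0.58), Zfand4 (-0.51) and the clock repressor Cry2 (-0.51) made up the rest of the 12. In the same samples 14 sinusoidal endothelial markers had a median log2 fold change of -0.25 (camera adjusted p = 1.02e-06, but adjusted p = 0.50 with an estimated correlation).

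Phf11c, Setdb2, Nox4, F2r and Gin1 stayed past the threshold whichever of the 8 arrays was left out. Without WT replicate 2 the adjusted p was 0.0789 for Map2k6, 0.106 for Dact1, 0.0807 for Pcp4l1, 0.141 for Arrdc2, 0.127 for Dnase1l3, 0.0869 for Zfand4 and 0.0684 for Cry2. Map2k6 also missed the threshold without WT replicate 3 (adjusted p = 0.0533), and Dact1, Arrdc2, Dnase1l3 and Zfand4 missed it without 4, 4, 4 and 3 further arrays. Arrdc2 also missed it when all probe sets were tested (adjusted p = 0.0514) and after quantile normalization (0.0546).

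Over all 19935 genes, 54 changed at an adjusted p under 0.05, of which 32 were higher and 22 lower in NS-DADm livers. At least 1.5-fold changes numbered 32, with 23 higher and 9 lower, and changes of at least 2-fold numbered 14, with 11 higher and 3 lower. Of genes named after their values were seen, Pvt1, Tgm1, Fgl1, Gstt3, Mmp9 and Id2 were among the other rises, with log2 fold changes of 0.72, 0.86, 0.80, 0.72, 0.58 and 0.56. Among the other falls were Pfkfb2 (-0.36), which regulates glycolysis, and Prodh2 (-0.47). In all 54 genes the 4 arrays of one group lay above the 4 of the other. A call at this threshold with 4 arrays per group nearly requires that separation, so it adds no evidence for the called genes. Over all genes it held for 5.63%, against 2.86% by chance. The median log2 fold change of all genes was -0.01. An unadjusted p under 0.05 was reached by 1859 genes, 9.33% of those tested. The count of changed genes depended on single arrays: it was 13 without WT replicate 2, 22 without WT replicate 3, 31 without NS-DADm replicate 2, 35 without NS-DADm replicate 3 and 126 without NS-DADm replicate 4. Leaving out NS-DADm replicate 4 also turned the share of higher genes from 59.3% to 46.8%.

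Genes that mouse liver expresses more in females than in males were higher in these male NS-DADm livers. Of 14 measured female-biased genes, 3 rose, namely Cyp2b9, Cyp17a1 (8.82 ± 0.14 to 10.41 ± 0.43, 3.01-fold, adjusted p = 0.00493) and Atp6v0d2 (6.89 ± 0.37 to 8.39 ± 0.12, 2.83-fold, adjusted p = 0.00364), and the same 3 when adjusted over the list alone. The median log2 fold change of the 14 was 0.26 (camera adjusted p = 4.03e-06, and adjusted p = 0.0391 with an estimated correlation), or 0.81 over those at or above the median level of all genes. That filter drops members low in both groups. It keeps Cyp2b9 and Atp6v0d2, whose WT means (6.35 and 6.89) lay below the array medians, so the filter itself raises the median. The other 11 of the 14 did not pass the test. Of these Abcd2 was at 0.81 (adjusted p = 0.502), Cyp2b13 at 0.42 (0.557), Acot3 at 0.34 (0.544), Fmo2 at 0.30 (0.415) and Hao2 at 0.22 (0.533), and the rest lay between -0.14 (Cyp3a44) and 0.04 (Cyp3a16), with Cyp3a16 and Sult3a1 near the low end of the intensities. Of 15 male-biased genes, 1, the cytochrome P450 gene Cyp2u1, fell, from 10.38 ± 0.11 to 9.91 ± 0.12 (log2 fold change -0.48, adjusted p = 0.032), and 5 were lower when adjusted over the list alone. The other 4 were Gstp1 (-0.43), Mup21 (-0.37), Slco1a1 (-0.29) and Cyp2d9 (-0.29). Of the 15 male-biased genes, 10 had values below 0 and 5 above 0. Those above 0 were Elovl3 (0.15), Nudt7 (0.09), Ugt2b38 (0.05), Cyp4a12a (0.03) and Ugt2b1 (0.00), none past the test. The male-biased list had a median of -0.29 (camera adjusted p = 0.00115, but adjusted p = 0.50 with an estimated correlation), or -0.15 without NS-DADm replicate 4, and an adjusted p of 0.071 with camera on ranks. Cyp2u1 missed the threshold without any 1 of 6 arrays, with an adjusted p of up to 0.166 (without WT replicate 2), and also after median subtraction (0.0553).

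Acute phase genes were higher as a group. All 21 measured members had a log2 fold change above 0, with a median of 0.24 and a mean of 0.59 (camera adjusted p = 1.32e-18, and adjusted p = 0.0391 with an estimated correlation). Of the 21, 3 rose over all genes and 10 when adjusted over the list alone. The 3 were Saa2, a serum amyloid A gene (8.87 ± 0.26 to 10.50 ± 0.55), Lcn2, an iron-siderophore binding lipocalin (8.71 ± 0.16 to 10.00 ± 0.55, adjusted p = 0.0479), and Orm2, an orosomucoid gene (9.60 ± 0.20 to 10.59 ± 0.21, adjusted p = 0.00718). The other 7 were Mt1 (log2 fold change 1.46), Saa1 (1.45), Mt2 (1.26), Orm3 (1.12), Apcs (0.87), Steap4 (0.82) and Hp (0.20). The fibrinogen genes Fga, Fgb and Fgg were at 0.18, 0.07 and 0.07, and Crp at 0.03, none past the test. Of 15 genes of inflammatory signalling, Il1b alone rose over all genes, from 6.26 ± 0.15 to 6.92 ± 0.17 (adjusted p = 0.0219), a level below the median of the arrays. Adjusted over the list alone, Il1b was higher and Nfkbia, which encodes an inhibitor of NF-kappaB, was lower (-0.30). The list's median was 0.18 (camera adjusted p = 0.000898, but adjusted p = 0.42 with an estimated correlation), or 0.28 without NS-DADm replicate 3, and was not called over genes at or above the median level (0.21). Il1b missed the threshold without WT replicate 2 (adjusted p = 0.121), WT replicate 3 (0.0786) or NS-DADm replicate 3 (0.061). In the same samples neutrophil markers had a median of 0.09, and Kupffer cell markers had one of 0.10, or -0.11 without NS-DADm replicate 4.

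**Figure D2:**
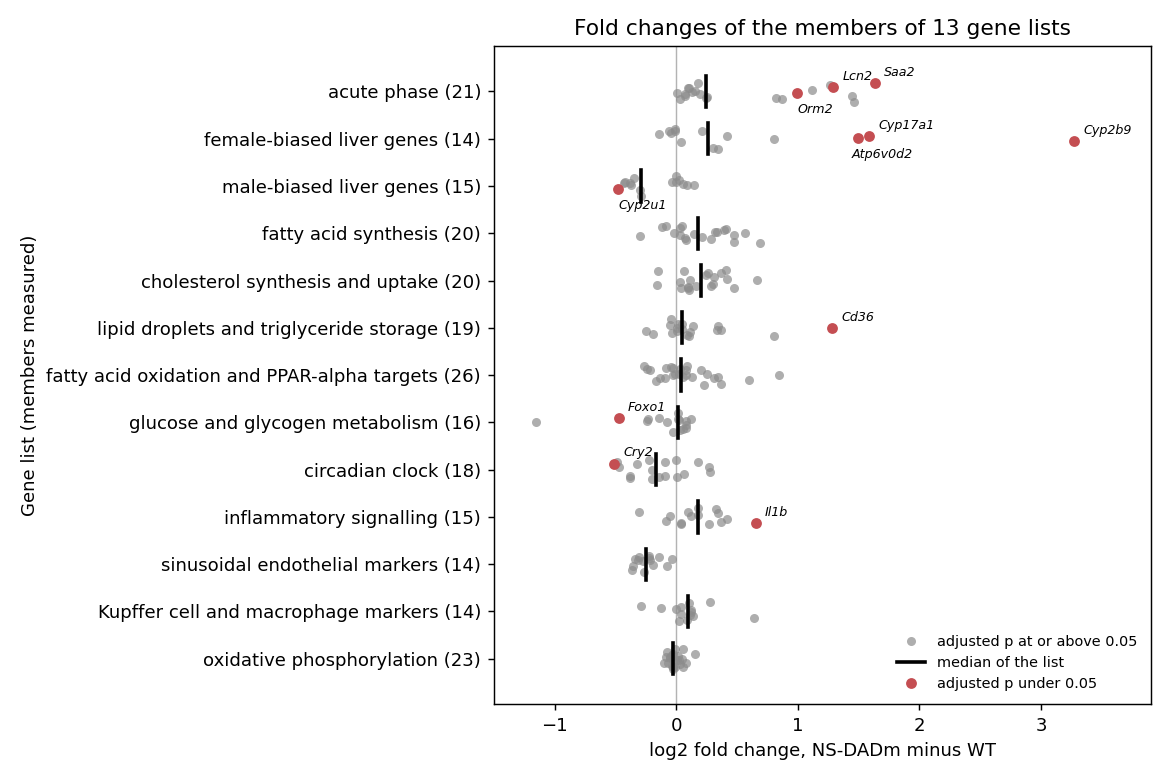
Log2 fold changes, NS-DADm minus WT (x axis), of the measured members of 13 gene lists (1 point per gene, 4 arrays per group), with a vertical bar at each list's median and red points for genes with an adjusted p under 0.05. All 21 acute phase genes lie above 0 and all 14 endothelial markers below 0, while oxidative phosphorylation genes centre on -0.02.

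Cd36 was the 1 of 19 genes of lipid droplets and triglyceride storage that rose over all genes. Fitm1 (0.80), which encodes an endoplasmic reticulum protein of lipid droplet formation, and Plin2 (0.34), which encodes a droplet coat protein, joined it when adjusted over the list alone. That list had a median of 0.05 (camera adjusted p = 0.0044, but adjusted p = 0.29 with an estimated correlation), and missed the threshold without NS-DADm replicate 4 (median 0.03, adjusted p = 0.131), with array weights (0.0592) and with camera on ranks (0.0593). The median was 0.08 without NS-DADm replicate 2 and 0.10 over genes at or above the median level. Pparg, the fatty acid-binding nuclear receptor, rose from 9.21 ± 0.13 to 9.84 ± 0.16 (log2 fold change 0.62, adjusted p = 0.0177) as the 1 changed gene of 6 adipose markers, also when adjusted over the list alone (list median 0.03, adjusted p = 0.183). The median of that list ran from -0.03 without WT replicate 4 (adjusted p = 0.581) and -0.01 without NS-DADm replicate 4 (0.467) to 0.09 without WT replicate 3 (0.0348). Pparg missed the threshold without WT replicate 1 (0.0609), 2 (0.0867) or 3 (0.0534) or NS-DADm replicate 3 (0.0645). No member of fatty acid synthesis changed over all genes, though 16 of 20 had values above 0. Acacb, an acetyl-CoA carboxylase gene, was at 0.69 (adjusted p = 0.217) and Mid1ip1 at 0.57 (adjusted p = 0.389), or 0.36 without NS-DADm replicate 1 and 0.24 as the mean of its probe sets. Adjusted over the list alone, Acacb was higher and Lpin1 (-0.30) lower. The list's median was 0.18 (camera adjusted p = 0.000173, but adjusted p = 0.50 with an estimated correlation). Its mean lay above all WT arrays (10.98 to 11.21) in NS-DADm replicates 1 and 2 (11.48 and 11.45). In NS-DADm replicates 3 and 4 (11.15 and 11.12) it lay within the WT range, and its exact permutation p was 0.171. Among 20 genes of cholesterol synthesis and uptake 18 were above 0, with none past the test over all genes or when adjusted over the list alone. Hmgcs1, of the mevalonate pathway, was at 0.66 (adjusted p = 0.263) and Idi1 at 0.48 (adjusted p = 0.468). This list's median was 0.20 (camera adjusted p = 5.88e-05, but adjusted p = 0.63 with an estimated correlation), or 0.12 without NS-DADm replicate 1. The exact permutation p of the list's mean was 0.257. In NS-DADm replicate 4 that mean, 10.55, lay below all WT arrays (10.66 to 10.84), against 10.95 to 11.22 in the other NS-DADm arrays. Without that array the list's median was 0.34, and Hmgcs1 (0.90), Idi1 (0.72) and Acacb (0.89) passed the test, with adjusted p of 0.00402, 0.00547 and 0.00912.

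Fatty acid oxidation and PPAR-alpha target genes had no member past the test over all 26, and 4 higher and 1 lower when adjusted over the list alone. Those were Vnn1 (0.60, adjusted p over all genes 0.0514), Ehhadh (0.36), Acaa1b (0.25) and Acadm (0.23), and the receptor gene Ppara itself (-0.22). Cyp4a14 had the largest value of the list, 0.85, with an adjusted p of 0.559. The list's median was 0.04 (camera adjusted p = 0.0201, but adjusted p = 0.67 with an estimated correlation). It missed the threshold without NS-DADm replicate 3 or 4 or WT replicate 1 or 3 (adjusted p = 0.151, 0.37, 0.123 and 0.0603), with a median of 0.03 without NS-DADm replicate 3. It also missed it with genes at or above the median level, quantile normalization, array weights, array spread as covariate and camera on ranks (adjusted p = 0.0537 to 0.149). Vnn1 passed the test without WT replicate 1 (adjusted p = 0.0414) and under 6 processing alternatives (0.0252 to 0.0454), and without that array Cyp4a14 was at 0.48.

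Of 18 circadian clock genes 1 fell, the repressor Cry2, from 9.55 ± 0.07 to 9.04 ± 0.10 (adjusted p = 0.0102). Adjusted over the list alone 5 were lower, Cry2, Usp2 (-0.49), Per1 (-0.38), Dbp (-0.32) and Hlf (-0.20), and 1, Clock (0.27), was higher. The median was -0.17 (camera adjusted p = 0.00444, but adjusted p = 0.50 with an estimated correlation and 0.054 with camera on ranks). All samples came from a single time of day, so phase and amplitude were not measured. Among 16 genes of glucose and glycogen metabolism Foxo1, a transcription factor that drives gluconeogenic genes, fell from 10.49 ± 0.08 to 10.02 ± 0.12 (adjusted p = 0.0256). Adjusted over the list alone 3 were lower, Foxo1, the glycogen-targeting gene Ppp1r3c (-1.16, adjusted p over all genes 0.0741) and the gluconeogenic enzyme gene Pck1 (-0.23). As a list these genes were not called (adjusted p = 0.376), with a median of 0.02, a mean of -0.11 and a downward camera statistic. Foxo1 missed the threshold without any 1 of 6 arrays, with an adjusted p of up to 0.127 (without WT replicate 2), and Cry2 missed it without WT replicate 2 (0.0684).

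Markers of sinusoidal endothelial cells were lower. All 14 had log2 fold changes below 0, from -0.36 to -0.04, with a median of -0.25 (camera adjusted p = 1.02e-06, but adjusted p = 0.50 with an estimated correlation). The mean of the 14 lay below all WT arrays (9.14 to 9.31) in 3 of 4 NS-DADm arrays (8.76 to 8.99) and within their range in NS-DADm replicate 4 (9.25), with an exact permutation p of 0.0857. None passed the test over all genes, and 8 were lower when adjusted over the list alone. Clec4g, a sinusoidal lectin gene, was at 11.20 ± 0.15 in WT and 10.83 ± 0.18 in NS-DADm livers (adjusted p = 0.238; a log2 fold change of -0.15 as the mean of its probe sets), and Oit3 was at 9.37 ± 0.11 and 9.01 ± 0.25 (adjusted p = 0.329). The others of the 8 were Bmp2, Kdr, Fcgr2b, Flt4, Stab2 and Stab1, from -0.33 to -0.23. Neutrophil markers were all above 0 in 10 of 10 genes, with S100a9 at 0.22 (adjusted p = 0.345) and S100a8 at 0.18 (adjusted p = 0.611). No neutrophil gene passed either test, also when adjusted over the list alone, and the median was 0.09 (camera adjusted p = 0.000856, but adjusted p = 0.50 with an estimated correlation). Their mean level, 6.38 ± 0.08 in NS-DADm and 6.27 ± 0.07 in WT samples, lay below the array medians, and the list missed the threshold without NS-DADm replicate 4 (adjusted p = 0.0727). Kupffer cell markers were not called as a list (14 genes, median 0.10, adjusted p = 0.138). That outcome depended on single arrays. The median was -0.11 without NS-DADm replicate 4, which had the highest mean of the list (9.60), and -0.03 without WT replicate 3. Leaving out NS-DADm replicate 1 or 2 or WT replicate 4 gave medians of 0.26, 0.15 and 0.19, and the list was then called (adjusted p = 0.000114, 0.0234 and 0.0117). None of them passed over all genes, and Mpeg1 (0.64, adjusted p over all genes 0.112, but 0.0475 with array weights and 0.0278 with the replicate block) was higher when adjusted over the list alone.

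Lymphocyte markers (median 0.06, adjusted p = 0.107), stellate cell and fibrosis genes (-0.05, 0.376), cholangiocyte markers (-0.03, 0.487) and pancreatic acinar markers (0.00, 0.618) had no member past the test over all genes or when adjusted over the list alone. The members with the largest values were Ptprc (0.32) and Nkg7 (0.30) of lymphocytes, Ecm1 (-0.48) and Lum (-0.41) of stellate cells, Muc1 (-0.22) and Pkhd1 (-0.17) of cholangiocytes, and Ctrb1 (0.04) and Cela2a (0.03) of acinar cells. Of 4 erythroid genes, too few to test as a list, none changed over all genes. Alas2, of haem synthesis, was at -0.51 (adjusted p = 0.0707), lower when adjusted over the list alone, and Slc4a1 was at 0.10. Without NS-DADm replicate 4 Ptprc was at 0.14 and Nkg7 at 0.09, stellate genes were called (median -0.13, adjusted p = 0.000356), and Ecm1 (-0.68, adjusted p = 0.046) and Alas2 (-0.59, 0.0153) passed the test. Without NS-DADm replicate 1 the stellate median was instead 0.01 (adjusted p = 0.951) and Ecm1 was at -0.30 (0.811), and without WT replicate 2 that median was -0.01. Lymphocyte markers were called without NS-DADm replicate 1 or 2 or WT replicate 1 (adjusted p = 0.00536, 0.0232 and 0.047), while their median was 0.02 without NS-DADm replicate 4 (0.93) and 0.04 without WT replicate 4 (0.336). With all probe sets the lymphocyte list was called (0.0244), and Alas2 passed the test under 3 processing alternatives (0.0372 to 0.047). Without WT replicate 4 Muc1 was at -0.12 and Pkhd1 at -0.03, which was -0.29 without WT replicate 2. Hepatocyte identity genes were not called as a list (14 genes, median 0.01, adjusted p = 0.229), with Alb at 0.01 and Hnf4a at 0.00. Onecut1 (0.77, adjusted p = 0.388) and Foxa3 (0.30) had the largest values there, and none passed either over all genes or when adjusted over the list alone. Foxa3 was at 0.19 without NS-DADm replicate 1.

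A few further lists were called with small medians. NRF2 targets (13 genes, median 0.05, camera adjusted p = 0.019, but adjusted p = 0.63 with an estimated correlation) had no changed member over all genes and 1, the quinone reductase gene Nqo1 (0.44, adjusted p = 0.0591), when adjusted over the list alone. Srxn1 was at 0.32. Cell cycle genes (23 genes, median 0.08, camera adjusted p = 0.0102, but adjusted p = 0.63 with an estimated correlation) had none over all genes, and Ccnd1 higher (0.46) and Ccne2 lower (-0.58) when adjusted over the list alone. Fetal liver genes (10 genes, median 0.04, camera adjusted p = 0.0452, but adjusted p = 0.50 with an estimated correlation) had none in either count, also when adjusted over the list alone, with Tff3 at 0.74 and Ly6d at 0.32. Without NS-DADm replicate 4 the adjusted p was 0.80 for NRF2 targets, whose median then was -0.05, 0.81 for cell cycle genes (median 0.03, against 0.13 without NS-DADm replicate 2) and 0.105 for fetal liver genes, Tff3 was at 0.24, and Nqo1 passed the test (adjusted p = 0.046). Nqo1 also passed it without WT replicate 4 (0.0452) and under 5 processing alternatives (0.0225 to 0.0496). NRF2 targets also missed the threshold without WT replicate 1 (0.0913) or 2 (0.0832), and fetal liver genes without NS-DADm replicate 2 (0.145) or WT replicate 1 (0.0913) or 2 (0.152). The fetal liver median ran from 0.02 without NS-DADm replicate 2 or WT replicate 2 to 0.09 without WT replicate 3, and was 0.07 without NS-DADm replicate 1 or 3 or WT replicate 1 or 4. The NRF2 median was 0.07 without WT replicate 3. Cell cycle genes were not called with either filter on low values or with array weights (adjusted p = 0.051 to 0.275), and NRF2 targets and fetal liver genes each missed the threshold under 6 processing alternatives (0.051 to 0.131 and 0.0554 to 0.158). Srxn1 was at 0.17 without NS-DADm replicate 1.

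Among lists tied to nuclear receptors, bile acid and sterol transport genes (median 0.01, adjusted p = 0.834), LXR targets (0.06, 0.748), thyroid hormone targets (-0.02, 0.565) and xenobiotic metabolism genes (-0.01, 0.427) were not called. Nr0b2, which encodes the repressor SHP, was at -0.79 and Cyp7a1, the rate-limiting enzyme gene of bile acid synthesis, at 0.56, neither past the test (adjusted p = 0.571 and 0.573), and at -0.45 without NS-DADm replicate 1 and 0.35 without WT replicate 4. No bile acid gene passed over all genes or when adjusted over the list alone. Of 13 LXR targets none changed over all genes and 4 were lower when adjusted over the list alone, Rgs16 (-0.80), Mylip (-0.39), Abcg5 (-0.26) and Abcg8 (-0.26). No thyroid hormone target passed over all genes or when adjusted over the list alone, with Bcl3 at 0.70 (adjusted p = 0.275) and Thrsp at 0.32. Thrsp ran from 0.17 without NS-DADm replicate 2 to 0.52 without NS-DADm replicate 4. Without NS-DADm replicate 1 Bcl3 was at 0.46 and Rgs16 at -0.99, past the test (adjusted p = 0.0453), and the LXR median was -0.07 without NS-DADm replicate 4. Of 19 xenobiotic metabolism genes Cyp2b9, also counted among the female-biased genes, was the 1 that rose, and Cyp1a1 (-0.28) joined it as lower when adjusted over the list alone. For bile acid genes the mean (-0.02) and camera (upward) differ in sign, for LXR targets the median is above 0 with a mean of -0.03, and for thyroid hormone and xenobiotic genes the median is below 0 with means of 0.07 and 0.22.

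Core hepatic and stress lists were not called. Histone deacetylases other than HDAC3 (13 genes, median -0.04, adjusted p = 0.551), endoplasmic reticulum stress genes (0.06, 0.251), heat shock genes (0.13, 0.0568) and oxidative phosphorylation genes (-0.02, 0.993) had no member past the test over all genes or when adjusted over the list alone. The same held for urea cycle and amino acid genes (0.01, 0.791). The largest values were Sirt3 (-0.22) and Sirt1 (-0.16) among deacetylases, Asns (0.92) and Atf3 (0.35) among stress genes, Hspb1 (-0.65) and Dnajb1 (0.57) among heat shock genes, Ndufs1 (0.15) and Sdhc (-0.10) in oxidative phosphorylation, and Tat (-0.20) and Gpt (-0.14) in amino acid metabolism. Single arrays carried some of these: Asns was at 0.39 without NS-DADm replicate 4, and Atf3 at 0.13, Dnajb1 at 0.25 and Tat at -0.12 without NS-DADm replicate 1. Ndufs1 was at 0.06 without NS-DADm replicate 3 and Gpt at -0.08 without WT replicate 1. The median of the endoplasmic reticulum stress genes ran from -0.01 without NS-DADm replicate 2 to 0.10 without NS-DADm replicate 4 or WT replicate 2. Heat shock genes were called without NS-DADm replicate 3 or 4 or WT replicate 2 or 4 (adjusted p = 0.0155 to 0.0362), and their median was 0.08 and 0.07 without NS-DADm replicate 2 and WT replicate 1. They were also called with all probe sets, trended and robust variances or array weights (adjusted p = 0.00804 to 0.0367). Apolipoproteins and related genes (-0.03, 0.834), interferon-induced genes (-0.01, 0.376), p53 targets (-0.05, 0.993), periportal genes (0.06, 0.455) and pericentral genes (-0.11, 0.308) also had no member past the test over all genes. Adjusted over the list alone Angptl8 (0.50) of the apolipoprotein list was higher, with Angptl4 at -0.17, and Irgm1 (0.45) of the interferon list was higher, with Cxcl10 at 0.40. Fas (0.33) was higher and Sesn2 (-0.37) lower among p53 targets, Sult5a1 (0.47) higher and Pck1 lower among periportal genes, with Aldh1b1 at 0.28, and Oat (0.45) higher among pericentral genes, with Glul at -0.25. Without NS-DADm replicate 4 Aldh1b1 was at 0.10 and Glul at -0.09, and Oat passed the test (adjusted p = 0.0254), as did Irgm1 without NS-DADm replicate 2 (0.0447) and Fas without WT replicate 4 (0.0353). Oat passed it under 3 processing alternatives (0.0177 to 0.0393) and Fas under 4 (0.0203 to 0.0467). The interferon list was called without NS-DADm replicate 2 (0.0217) and the pericentral list without NS-DADm replicate 3 (0.0283). In 5 of these lists the mean or camera differs in sign from the median: for interferon-induced genes the mean was 0.05 and camera upward, for oxidative phosphorylation and p53 targets camera was upward, and for apolipoproteins the mean was above 0 with camera downward. For urea cycle and amino acid genes the mean was -0.01 with camera upward.

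In total 14 of 36 lists were called, 11 upward and 3 downward. With the correlation between genes estimated from the data, 2 of the 14 calls held, those of the acute phase and female-biased lists. Of the lists not called, 16 had a median that turned sign under at least 1 alternative. Genes named only for the count adjusted over their list were chosen after their values were seen.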

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

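In this part, the tests of fewer non-hepatocyte cells and of array spread were chosen only after the result was seen, as was the check of a correlation without 2 arrays. Phf11c and Setdb2 were picked by their falls in these data, so the tests of that pair also followed those falls. Samples far from the rest of their group were sought by setting the gap between the farthest of 4 arrays and its nearest neighbour against the range of the group, with Dixon's 95% critical value as the limit. Chance passes that limit in about 1 of 20 groups. Here 14 of 254 groups passed, against 12.7 by chance, so the number of such arrays is about what chance gives. NS-DADm replicate 4 was the far array in 4 of the 14.

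Phf11c and Setdb2, the neighbouring genes with the largest falls, both had WT replicate 4 lowest, at 9.66 for Phf11c against 10.22 to 10.32 in the other WT arrays (gap over range 0.84) and at 9.76 for Setdb2 against 10.22 to 10.30 (0.862). A donor-strain segment carried along with the mutated genes is argued against, since the pair lies on a chromosome other than those of the mutated genes. Of the 200 tested genes nearest to the mutated genes 0 changed. With only 54 changed among 19849 genes of known position, few would be found there by chance, so that count adds little. A deletion or strain segment around the pair cannot be told apart from regulation of these genes, because 2 of the 20 nearest tested genes, Rcbtb1 (-0.34) and Cab39l (-0.14), were lower in all NS-DADm arrays than in all WT arrays, between the 1 and 3 set as limits. That 1 transcript is read by both probe sets may explain their joint fall but also stays open: deviations from the group means correlated over the 8 arrays (Pearson r = 0.859, exact permutation p = 0.0208; Spearman rho = 0.571, p = 0.151), yet r was 0.327 without WT replicates 3 and 4, so the relation rests on those arrays. Whether and how these falls follow from the loss of deacetylase activation was not tested.

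Clec4g, the endothelial marker with the lowest value, had NS-DADm replicate 1 lowest, at 10.56 against 10.92 to 10.93 (0.965), within a list of 14 markers whose group means were all lower in NS-DADm samples, although the list's mean in NS-DADm replicate 4 (9.25) lay in the WT range (9.14 to 9.31) and its own exact permutation p was 0.0857. Differences in the spread of the arrays are argued against, since the list's median stayed at -0.245 after quantile normalization. Fewer non-hepatocyte cells of every kind could not be told apart from a change in endothelial cells alone. The means of Kupffer cell and lymphocyte markers were 0.09 and 0.09 higher in NS-DADm samples (exact permutation p = 0.686 and 0.486). The Kupffer cell median, however, was -0.11 without NS-DADm replicate 4. The endothelial mean minus the mean of both differed by -0.33 between NS-DADm and WT samples. Its exact permutation p was 0.0571, where 4 against 4 arrays allow 0.0286 at the smallest. A smaller share of sinusoidal endothelial cells stays open. The SD of the markers' log2 fold changes was 0.979 times their median SE, within the limit set for this explanation. Noise around any common shift can give such a ratio, and the markers vary together (estimated correlation 0.557). The ratio therefore cannot tell a smaller share of cells from lower transcription in each cell. Lower transcription of these genes within endothelial cells was not tested.

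The remaining far arrays are given as values. In Nox4, NS-DADm replicate 3 was highest at 9.44 against 9.05 to 9.10 (0.874). In Zfand4, WT replicate 1 was lowest at 8.90 against 9.16 to 9.21 (0.844). Cyp2u1 was lowest in WT replicate 3, at 10.22 against 10.42 to 10.45 (0.869). Glul, the pericentral glutamine synthetase gene, was lowest in NS-DADm replicate 4 at 12.03 against 12.63 to 12.74 (0.849). Tff3 was highest in NS-DADm replicate 4 at 10.80 against 8.71 to 8.94 (0.893). Irgm1 was lowest in NS-DADm replicate 2 at 9.73 against 9.99 to 10.01 (0.932). S100a9 was highest in NS-DADm replicate 4 at 7.02 against 6.89 to 6.91 (0.865). List means stood apart for glucose metabolism genes, lowest in WT replicate 1 (11.47 against 11.57 to 11.59, 0.847), and for LXR targets, highest in NS-DADm replicate 4 (10.73 against 10.62 to 10.63, 0.963). They also did for acute phase genes, lowest in WT replicate 4 (10.71 against 10.76 to 10.77, 0.848), and for interferon-induced genes, lowest in WT replicate 1 (8.21 against 8.34 in the other arrays, 0.956).

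Signal also lay outside the gene table. When all probe sets were tested, 3 probe sets that name several genes changed (1 higher, 2 lower) and 4 unnamed probe sets changed (1 higher, 3 lower), with log2 fold changes from -1.19 to 0.72.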

How the results depend on the processing

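The fit with array spread as a covariate was chosen only after the data were seen. The 54 changed genes became 45 to 60 with all probe sets, the mean of probe sets, either filter, quantile normalization, median subtraction or trended and robust variances, and 77 with array spread as covariate. Array weights gave 109 and thresholds of 0.01 and 0.1 gave 13 and 109. The gene-by-gene test without shared variances gave 0 changed genes and 0 changed at least 1.5-fold, with 1709 at an unadjusted p under 0.05 against 1859 in limma; it estimates each variance from 8 arrays alone. Leaving out each array gave 13 (without WT replicate 2) to 126 (without NS-DADm replicate 4) changed genes, 12 to 61 changed at least 1.5-fold, and a share of higher genes of 46.8% to 70.7%, below 50% only without NS-DADm replicate 4. The causes were not tested. With the replicate number as a block, 105 genes changed, 52 of them at least 1.5-fold, and 49 of the 54 calls were kept. Same-numbered arrays correlated in their deviations from the group means at 0.146, 0.0483, -0.102 and 0.247. NS-DADm replicates 1 and 4 correlated best with the WT array of their own number. NS-DADm replicate 2 correlated best with WT replicate 1 (0.247) and NS-DADm replicate 3 with WT replicate 4 (0.258). These few correlations neither show nor exclude a pairing or shared batch by number. The 14 called lists became 8 with genes at or above the median level, where fewer genes are tested, 8 with camera on ranks and 2 with an estimated correlation, which allows for genes that vary together. Camera was not run for the gene-by-gene test. None of the changed named genes turned its direction under any alternative run, and no called list turned the direction of its camera test. The median of 1 called list, NRF2 targets, turned sign (-0.05 without NS-DADm replicate 4), as did the values of 3 named genes past no test and near 0 (Gps2, Ctrb1 and Cela2a) and the medians of 16 lists not called. Among them Kupffer cell markers went from 0.10 to -0.11 without NS-DADm replicate 4. Processing alternatives ended the calls of Cyp2b9 and Saa2 (trended and robust variances), Lcn2 (adjusted p = 0.0505 to 0.125 under 6), Cyp2c38 (3), Arrdc2 (2) and Cyp2u1 (median subtraction). The replicate block made Onecut1, Hspb1, Mpeg1 and Clec4g pass the test (adjusted p = 0.026, 0.0337, 0.0278 and 0.0421). Of 696 values of named genes with an array left out, 64 lost and 12 gained a call, and of 946 under the other alternatives 43 lost and 26 gained one. For lists, 14 lost and 14 gained a call of 288 with an array left out, and 37 lost and 4 gained one of 425 under the others. Acute phase and female-biased genes were called in all 20 alternatives. Signal over background was not given, so changes of genes near the low end, such as Il1b, are least certain.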

Other observations

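In this part, the tests of neighbouring genes were chosen only after the result was seen. Some changed genes belong to none of the lists. The glutathione transferases Gstt3 (0.72) and Gstt1 (0.36), the sulfotransferase Sult1a1 (0.50) and the arsenic methyltransferase As3mt (0.49) were higher in NS-DADm livers, as was Hacl1 (0.51), of fatty acid alpha-oxidation in peroxisomes. Hjv, the hemojuvelin gene that controls hepcidin, rose by 0.64, Id2 by 0.56 and Mmp9 by 0.58. Lower were Plxnc1 (-0.46), Rogdi (-0.42), Tmem86b (-0.41), Srsf4 (-0.34) and Stk35 (-0.33). All have adjusted p under 0.05 in limma and were named after their values were seen.

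Among the 54 changed genes 5 pairs lay at most 5 tested genes apart, namely Gstt3 and Gstt1, Phf11c and Setdb2, Cyp2c38 and Cyp2c39, Cyp17a1 and As3mt, and Il1b and Stk35, the last moving in opposite directions. Random draws of 54 genes gave a mean of 0.705 pairs (10000 draws, permutation p = 8e-04). Phf11c and Setdb2 prompted the test, though, and Gstt3 and Gstt1, and Cyp2c38 and Cyp2c39, are paralogs whose probes may share signal. With 1 gene of each of these 3 pairs left out, 2 pairs remained against a mean of 0.622 in random draws of 51 genes (permutation p = 0.128), so random placement is not excluded for the rest.

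The direction of the sex-biased genes in these male livers was weighed as a hypothesis. Female animals among the NS-DADm samples are argued against, since Xist and the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty ranged over at most 0.285 on the log2 scale across the 8 arrays. Cross-hybridisation within cytochrome P450 families as the whole cause is also argued against, since the female-biased list without members of the Cyp2, Cyp3 and Cyp4 families (10 genes, median 0.26) had a camera p of 5.62e-06, and 0.00319 with an estimated correlation. A partial loss of the male pattern of liver expression in NS-DADm mice is a hypothesis these values may fit. The same samples were used to find it. However, the male-biased list without those families had a camera p of 0.208 with an estimated correlation. In addition, 5 of the 15 male-biased genes, among them Elovl3 (0.15) and Cyp4a12a (0.03), had values above 0. Changes in growth hormone secretion or signalling were not measured.

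Other splits of the 8 arrays into 4 and 4 number 35 with the real one. The 54 changed genes were reached by 1 of 35, the real split, and the highest other split gave 1, with 33 splits giving 0. Changes of at least 1.5-fold gave the same count, 1 of 35, with 32 against 1. This argues against chance for both counts but cannot exclude it, since 1 of 35 is the smallest share these splits allow. The other splits also mix arrays of both groups, so a real group difference adds to their spread and lowers their counts. The share of higher genes could not be tested by splits: 33 of 35 have no called gene, and the other split, with 1 called gene, lies 50 points from 50% whatever its direction, which makes 2 of 35 splits at least as far as the real one (9.26 points). As many as 14 called lists came in 6 of 35 splits, with 17 at the highest and a median of 9 in the others, so chance is not excluded for the number of lists. For acute phase genes and for female-biased genes 1 of 35 splits, the real one, gave an adjusted p as small. An exact permutation test of list means gave its smallest possible p, 0.0286, for 6 of 38 lists, and 0.181 after adjustment over the 38. These were both lists above (NS-DADm minus WT 0.59 and 0.59), the HDAC3 complex (0.21), inflammatory signalling (0.17), lipid droplets (0.17) and erythroid genes (-0.09). The erythroid mean was lowered by Alas2 (-0.51), while 3 of the 4 genes were above 0. The HDAC3 complex mean was raised most by Tbl1xr1 (0.61), with Tbl1x at 0.20, Hdac3 at 0.09 and Gps2 at -0.04. No list can go below 0.0286, so a few lists at that value cannot pass an adjustment over 38. The test therefore could not have singled out any list.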
